A study of Mus musculus with 5 samples.

How the data were processed

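RNA from sorted cells of mdx muscle was hybridised to 5 Agilent arrays of 1 colour, 2 for Sca1+ cells with vehicle, 2 for Sca1+ cells with TSA and 1 for MuSC with vehicle. Per the file headers, each array's spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted the background and detrended the processed intensity within the array, without scaling between arrays. The deposited table of processed values is in log2: set against each array's spot values, its columns had a Spearman correlation of at least 0.9998, a shared median of 4.67 and sorted values equal within 0.00127, as quantile normalization of the log2 processed signal gives. The tool used for it is not stated.

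The values used were log2 of the processed signal minus each array's 75th percentile of it over the 59305 non-control spots. Control spots and spots marked as outliers by the extraction software (0.196% to 0.334% per array) were left out, and spots of 1 probe were averaged. Of 55681 probes, 26413 were named through their accession in a RefSeq gene table and 574 through another probe of the same design name; the others kept the name of the array design, which can be old. For a gene with several probes, the probe with the highest mean over all arrays was taken. Of 36409 genes and unnamed features, 26117 were kept because they were well above background on every array of at least 1 group. Probe positions are those of the array files, in mm9; no genome was used here.

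Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05) over all 5 arrays in 3 groups, which left 2 residual degrees of freedom and a prior of 2.30. The error printed with a log2 difference is the model's standard error. Where a probe was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value among probes well above background. This bound concerns the background only and not the spread between arrays, so a single slide can lie below it. It equals the fitted fold where the probe's own values lie above that lowest value. Before the data were examined, 29 gene lists were fixed, to be tested with camera. They covered the sorting gate, satellite cells, myogenic differentiation and sarcomere, fibroadipogenic progenitors, collagens and matrix, matrix proteases, TGF-beta signalling, adipogenesis, paracrine regulators, histone deacetylases, SWI/SNF, genes often raised by histone deacetylase inhibitors, cell cycle, interferon response, chemokines, complement, immediate early and heat shock genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, sex-linked genes, and markers of endothelial cells, macrophages, lymphocytes, granulocytes and mast cells, pericytes and smooth muscle, Schwann cells, tendon cells and red cells (preset inter-gene correlation 0.01, adjusted over the lists). No list call held with an estimated correlation in either comparison. That estimate rests on 2 residual degrees of freedom, which leaves the test little power. A call lost there does not show that a list was unchanged. Genes were named by a rule fixed at the same time: of genes with a symbol (other than Rik, Gm and LOC names) past the threshold and of the same sign on both slides (for MuSC, beyond both vehicle arrays), the 12 largest differences in each direction, filled up to 8 at an unadjusted p under 0.01 where fewer passed, 12 genes set by name, and 2 to 4 members with the largest change of each list described; some of these members are not reported here.

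The arrays lay on 2 slides, replicate 1 of each group on the first. Labels do not say what a replicate number shares, and 2 pairs are too few to settle whether numbers pair samples. Replicate arrays correlated at 0.987 (vehicle) and 0.989 (TSA). On 327 probes printed more than once, they differed with an SD of 0.137 and 0.210 on the log2 scale, while spots of a probe within an array differed with a median SD of 0.0632 to 0.0797. Replicates were counted as separate samples, which the values cannot settle.

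The methods were tested on simulated data drawn from the means of 26105 genes, with 200 genes changed. For TSA against vehicle, 0% of changes of 1 log2 unit and of 2 were called and 91.6% of changes of 4, with 5.38% false among the calls. For MuSC against Sca1+ cells the shares were 0%, 0% and 85.8%, with 5.80% false at 4. With 200 genes changed, the adjusted threshold is stricter than in the data, where 778 genes passed for TSA. The data hold smaller calls, such as Fosl1 at 1.25, so these shares are not the power of the real comparisons. A list of changed genes was found by camera in 5 of 5 simulations at each size. A list of unchanged genes was called in 1 of 5 for MuSC at a change of 1, and in 0 at the other sizes and for TSA. For MuSC at a change of 1, the false share of gene calls averaged 20% over the 5 runs, with a run without calls counted as 0%. The simulated noise was independent between genes, so these runs do not test the preset inter-gene correlation. Alternatives were normexp background correction with an offset of 50, quantile normalization, the percentile over probes above background on all arrays, other filters on dim probes, outlier spots kept, each probe alone, the mean of a gene's probes, the slide as a block, an intensity trend in eBayes, the deposited values, each Sca1+ array left out in turn, and an estimated correlation or fry for the lists. Figures were drawn with matplotlib 3.10.9.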

Results

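Gene expression was measured in cells sorted from the muscles of mdx mice, which carry a mutation in the dystrophin gene and serve as a model of Duchenne muscular dystrophy. The mice had received trichostatin A (TSA), an inhibitor of histone deacetylases, at 0.6 mg per kg, or its vehicle, for 45 days. The labels give 2 sorted populations. Both were gated on CD34 and α7-integrin, and they differ in Sca1, the surface protein encoded by Ly6a: Sca1-positive interstitial cells (Sca1+ cells), and Sca1-negative muscle stem cells (MuSC). Sca1+ cells were hybridised to 2 arrays with vehicle and 2 with TSA, and MuSC to 1 array with vehicle. Replicate 1 of each group lay on slide 1 and replicate 2 on slide 2. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Between 58.5% and 66.9% of probe spots were well above background on an array, and no spot was saturated. The 75th percentile of the processed signal was 235 and 165 on the vehicle arrays, 326 and 452 on the TSA arrays and 240 on the MuSC array. The number of arrays limits the precision.

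The first comparison asked which genes differed in Sca1+ cells between TSA and vehicle. Of the genes in lists fixed in advance, 8 of 14 of pericytes and smooth muscle, 22 of 35 of myogenic differentiation and the sarcomere, 8 of 24 of satellite cells, 4 of 12 of granulocytes and mast cells and 4 of 5 of red blood cells were called higher with TSA. The camera calls of these 5 lists were lost with an estimated correlation (adjusted p between 0.161 and 0.316). That correlation was estimated from 2 residual degrees of freedom, so the loss does not show that a list was unchanged. Cnn1, which encodes the smooth muscle protein calponin, was higher by 6.12 ± 0.16 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 0.0036). Its probe lies on chromosome 9 at 21913058 to 21913117 in mm9. Genes of fibroadipogenic progenitors, the fibroblast-like cells that express Pdgfra, had a median log2 difference of −0.83. In all, 708 genes were higher and 70 lower of 26117 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 778 of these 778 had the same sign on both slides. A gene passes only where the arrays of a group lie close together, so this agreement follows largely from the choice of genes and is no replication. Leaving out either TSA array left 0 genes past the threshold in limma, with 4923 genes at an unadjusted p under 0.05 without replicate 1 and 3101 without replicate 2, and leaving out a vehicle array left 318 higher and 2 lower without replicate 1, and 254 and 2 without replicate 2. With normexp background correction the split turned to 1311 higher and 6526 lower, while the median log2 difference of all genes moved from −0.13 to −0.26; among called genes that differed at least 2-fold, 464 were then higher and 103 lower.

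**Figure D1:**
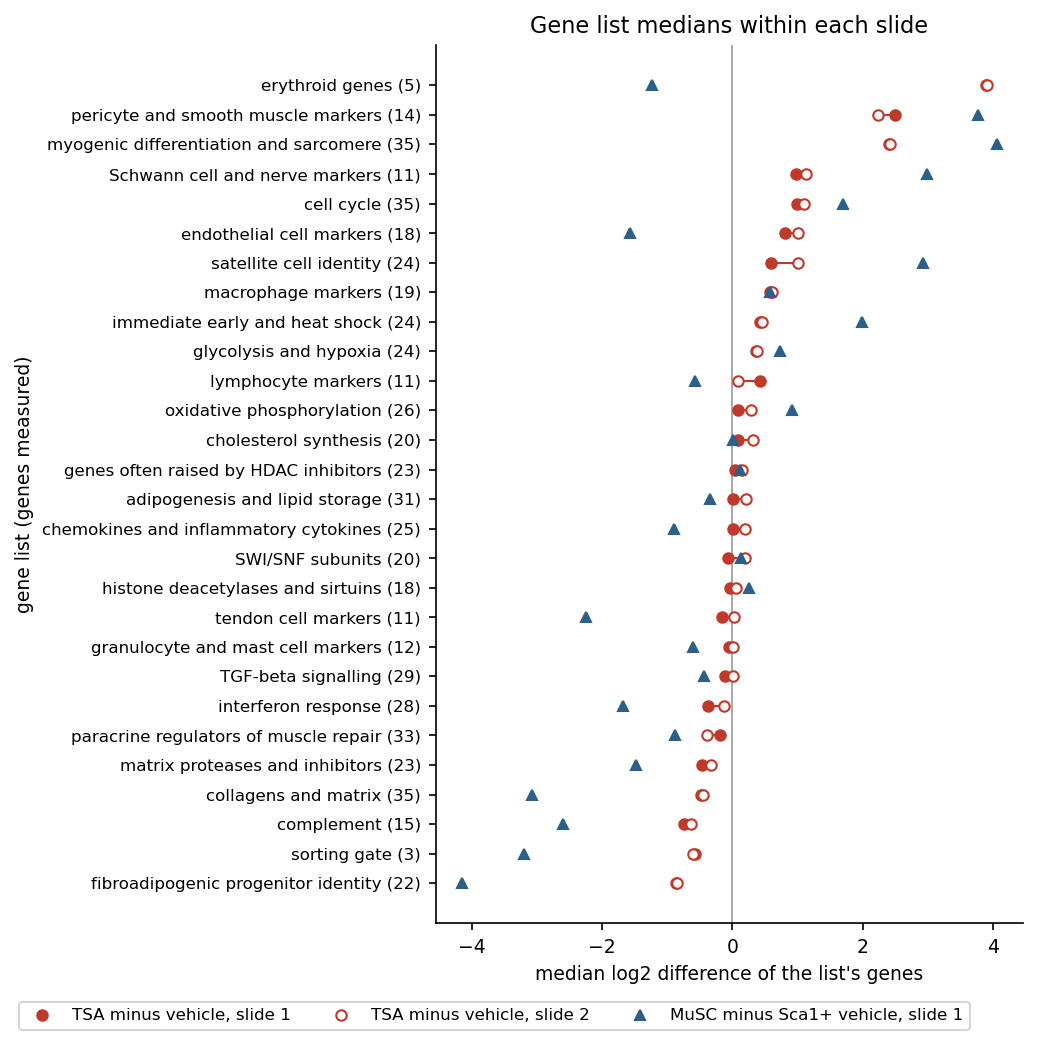
Median log2 difference (horizontal axis) of the genes in each list fixed in advance except the sex-linked genes (vertical axis, with the number of genes measured). Filled and open circles give TSA minus vehicle in Sca1+ cells on slide 1 and slide 2, joined by a line, and triangles give MuSC minus vehicle Sca1+ cells on slide 1; the sarcomere list lies at 2.41 and 2.42 on the 2 slides, and the fibroadipogenic progenitor list at −0.87 and −0.86.

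Of the 12 genes with the largest increase, several belong to smooth muscle. Pln (phospholamban, a regulator of the calcium pump of the sarcoplasmic reticulum), Olfr78 (an olfactory receptor family member) and Iqsec3 were not well above background on either vehicle array and were at least 89.5-fold, 87.0-fold and 86.9-fold higher with TSA. These bounds are fitted means: on slides 1 and 2 the log2 difference was 5.45 and 7.44 for Olfr78, and 5.70 and 7.19 for Iqsec3. Myocd, a transcriptional coactivator of smooth muscle genes, was at least 59.0-fold higher and Lmod1, an actin-binding protein of smooth muscle, at least 55.9-fold. Chrdl2, a secreted antagonist of bone morphogenetic proteins, was at least 58.7-fold higher. Adjusted p (limma) for these 6 genes lay between 0.0036 and 0.0317. The other genes of this group were Cpa3 (log2 difference 6.89 ± 0.63), Mcpt4 (5.92 ± 0.15) and Mcpt-ps1 (5.86 ± 0.21), genes of mast cell proteases, Fcer1a, a chain of the IgE receptor, at least 60.6-fold higher, and Jchain, the joining chain of secreted immunoglobulins, at least 52.3-fold higher. Cpa3 was well above background on 1 of the 2 vehicle arrays.

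Decreases were smaller. Krtdap and Dmkn, neighbouring genes on chromosome 7 expressed in skin keratinocytes, differed by −2.66 ± 0.16 and −1.83 ± 0.19. Ttll2 was not well above background with TSA and was at least 5.57-fold lower (log2 difference −1.98 on slide 1 and −2.98 on slide 2), and Ppp1r3g at least 3.02-fold lower. Unc93a differed by −2.21, Syt13 by −1.92, Pcdh20 by −1.77, Igsf1 by −1.76 (−0.39 by another of its probes), Smpd3 by −1.72 and Scara5, a ferritin receptor, by −1.57. The chemokine Cxcl13 differed by −1.69 and the chemokine-scavenging receptor Ackr2 by −1.65. Adjusted p (limma) for these 12 genes lay between 0.00749 and 0.043.

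Of 35 genes of myogenic differentiation and the sarcomere, 22 were higher and 0 lower (31 higher and 0 lower when adjusted over the list alone), with a median log2 difference of 2.35. Actc1 (cardiac actin, also expressed in embryonic muscle) was higher by 4.93 ± 0.16, the myogenic transcription factor Myog by 4.89 ± 0.20 and the calcium-binding protein Casq2 by 4.54 ± 0.15. Of 24 satellite cell genes, 8 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.83. Calcr, the calcitonin receptor of quiescent satellite cells, was at least 20.8-fold higher, and Chrna1 and Cdh15 were higher by 4.48 ± 0.15 and 4.36 ± 0.22. Of the genes fixed by name, Pax7 and Myod1, transcription factors of satellite cells and of myogenic commitment, rose by 3.07 ± 0.29 (adjusted p = 0.0212) and 3.09 ± 0.39 (adjusted p = 0.0394), and Pax7 was well above background on 1 of the 2 vehicle arrays. Myf5 was not well above background on either vehicle array, at least 3.86-fold higher, and did not pass (adjusted p = 0.113; 0.0457 with the slide as a replicate block). Adjusted p of camera over the lists was 1.11e-27 for the sarcomere list and 2.73e-07 for the satellite cell list (0.161 and 0.171 with an estimated correlation).

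Markers of other cell types were read beside these lists. Of 14 pericyte and smooth muscle genes, 8 were higher and 0 lower, 11 and 0 adjusted over the list alone (median 2.36; camera adjusted p = 5.97e-14, and p = 0.161 with an estimated correlation); Myh11, smooth muscle myosin, was higher by 5.74 ± 0.16 and Acta2, smooth muscle actin, by 4.57 ± 0.14. Of 11 Schwann cell and nerve genes, 5 were higher, 7 adjusted over the list alone (median 1.04; camera adjusted p = 2.59e-08, and p = 0.161 with an estimated correlation); Mal, which encodes a membrane raft protein, was higher by 4.44 ± 0.23, while probes of Mbp ranged from −0.71 to 1.94. Of 5 erythroid genes, 4 were higher, also 4 adjusted over the list alone, with a median of 3.92 (camera adjusted p = 2.43e-07, and p = 0.161 with an estimated correlation): Alas2, which starts haem synthesis in red cells, rose by 4.41 ± 0.21 and the globins Hbb-b2 and Hba-a1 by 4.02 ± 0.18 and 3.92 ± 0.15. Globin copies are near-identical and their probes may not tell them apart. Of 12 granulocyte and mast cell genes, 4 were higher, also 4 adjusted over the list alone, all of mast cells, including Cma1 at least 53.0-fold; the median was −0.08 and the mean 1.54 (camera adjusted p = 0.0422, direction up; p = 0.316 with an estimated correlation). Of 18 endothelial genes, 1 was higher, 13 adjusted over the list alone (median 0.90; camera adjusted p = 9.47e-09, and p = 0.161 with an estimated correlation), and Vwf, von Willebrand factor, rose by 2.96 ± 0.15. None of 19 macrophage genes passed, and 7 passed as higher adjusted over the list alone (median 0.59; camera adjusted p = 6.77e-06, and p = 0.171 with an estimated correlation).

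Of 22 fibroadipogenic progenitor genes, 1 was lower, Pi16 at −1.37 ± 0.18, and 17 were lower adjusted over the list alone (camera adjusted p = 3.08e-08, and p = 0.161 with an estimated correlation). Pdgfra differed by −0.80 ± 0.18 (limma adjusted p = 0.121). Of 35 genes in the list of collagens and matrix 0 passed in limma, and 10 were lower and 1 higher adjusted over the list alone (median −0.50; camera adjusted p = 5.73e-05, and p = 0.223 with an estimated correlation); with normexp the camera adjusted p was 0.365. Of 35 cell cycle genes, 6 were higher, 33 adjusted over the list alone (median 1.02; camera adjusted p = 1.70e-19, and p = 0.171 with an estimated correlation), including the cyclin gene Ccnb1 at 1.48 ± 0.17 and Rrm2, a ribonucleotide reductase subunit, at 1.42 ± 0.16. Of 24 immediate early and heat shock genes, 2 were higher, Fosl1 at 1.25 ± 0.14 and Nr4a1 at 1.24 ± 0.15, and 7 adjusted over the list alone (median 0.38; camera adjusted p = 1.89e-07, and p = 0.171 with an estimated correlation). None of 23 genes often raised by histone deacetylase inhibitors passed, with 2 higher and 1 lower adjusted over the list alone (median 0.16; camera adjusted p = 0.0651, and p = 0.370 with an estimated correlation). None of 18 histone deacetylase and sirtuin genes passed, 1 being higher adjusted over the list alone (median 0.02; camera adjusted p = 0.379).

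Genes of the sorting gate and of regulators fixed by name were read next. Itga7, which encodes the α7-integrin of the gate, was higher with TSA by 3.34 ± 0.17 (adjusted p = 0.00539). Ly6a and Cd34 differed by −0.73 ± 0.16 and −0.72 ± 0.16 and did not pass (adjusted p = 0.115 and 0.114), while both passed as lower when adjusted over the list alone, the 3 genes of the sorting gate. Smarcd3, the BAF60C subunit of the SWI/SNF chromatin remodelling complex, was 2.84-fold higher (adjusted p = 0.0337); Smarcd1 and Smarcd2 differed by −0.19 ± 0.18 and −0.18 ± 0.20 (adjusted p = 0.536 and 0.602). Smarcd3 was the only 1 of 20 SWI/SNF genes to pass. Fst, the secreted myostatin antagonist follistatin, differed by −1.19 ± 0.35 (adjusted p = 0.163; 0.0489 with the slide as a replicate block). The chosen Dmd probe was not well above background on either vehicle array and was at least 3.73-fold higher (adjusted p = 0.0176), its probes ranged in fitted log2 difference from 0.58 to 3.29, and with normexp it differed by −0.19.

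**Figure D2:**
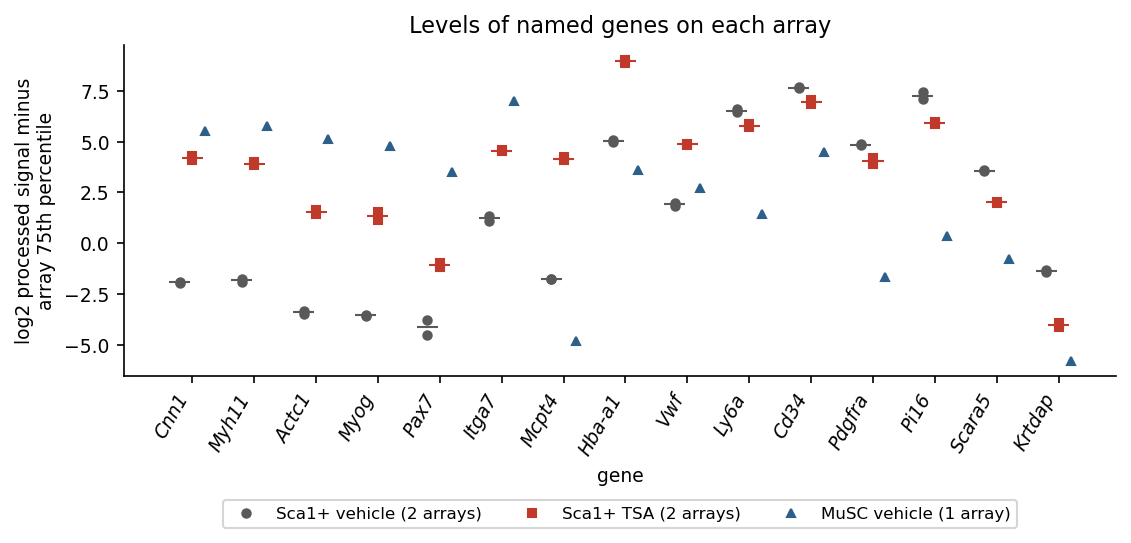
Level of named genes (horizontal axis) on each array, as log2 processed signal minus the array's 75th percentile (vertical axis). Circles are the 2 vehicle Sca1+ arrays, squares the 2 TSA Sca1+ arrays and triangles the MuSC array, with a bar at the mean of each pair; Cnn1, at 6.12 log2 units above vehicle, and Itga7, at 3.34, lay between vehicle Sca1+ cells and MuSC, while Mcpt4 was higher with TSA than in either.

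The second comparison set MuSC against vehicle Sca1+ cells. MuSC held more transcripts of satellite cells and of muscle, and Sca1+ cells more of matrix and of fibroadipogenic progenitors. In MuSC 2738 genes were higher and 3045 lower of 26112 tested (limma, adjusted p under 0.05), with 1 MuSC array assumed to vary like the Sca1+ arrays. Without replicate 2 of vehicle Sca1+ cells, 1608 were higher and 1840 lower, and without either TSA array 1590 and 1833. Vgll2, a cofactor of muscle transcription, was at least 492-fold higher, Calcr at least 448-fold and Popdc3 at least 399-fold. Chrdl2 was at least 1275-fold and Iqsec3 at least 972-fold higher, Bves at least 383-fold and Pln at least 305-fold. Log2 differences were 8.83 ± 1.43 for the embryonic myosin gene Myh3, which was well above background on 1 of the 2 vehicle Sca1+ arrays, 8.53 ± 0.20 for Actc1, 8.36 ± 0.25 for Myog and 8.29 ± 0.27 for Cdh15. Trim6 was at least 1854-fold higher by 1 probe (log2 difference 10.86 ± 0.61), its other probes not being well above background on the MuSC array. In the other direction, Pi16 (−6.91 ± 0.22), Lum (−6.75 ± 0.20), Mmp3 (−6.69 ± 0.20), Sfrp4 (−6.67 ± 0.22), C3 (−6.65 ± 0.18), Pdgfra (−6.49 ± 0.23), Gdf10 (−6.34 ± 0.28) and Col14a1 (−6.32 ± 0.19) were lower, and Tspan11 was at least 114-fold lower. By another probe, C3 differed by −5.76 and Col14a1 by −4.27. Inmt, Dpep1 and Kcp differed by −6.86, −6.85 and −6.46. Adjusted p for the named genes lay between 0.00142 and 0.0199.

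Of the 24 satellite cell genes 19 were higher in MuSC, and of the 35 sarcomere genes 34 (medians 3.16 and 4.12; 19 and 34 adjusted over the list alone). Of 22 fibroadipogenic progenitor genes 21 were lower, and of 35 collagen and matrix genes 33 (medians −4.10 and −3.06; 21 and 34 adjusted over the list alone, with 1 matrix gene higher). Pericyte and smooth muscle genes were higher as well, 13 of 14 with 1 lower (also 13 and 1 adjusted over the list alone), with Myh11 at 7.59 ± 0.19, and so were 8 of 11 Schwann cell genes (9 adjusted over the list alone). Adjusted p of camera for these 6 lists lay between 1.81e-23 and 1.79e-07, and was 0.118 for each with an estimated correlation. Endothelial genes were lower, 15 of 18 with 1 higher, and 15 with 2 higher adjusted over the list alone (median −1.45; camera adjusted p = 2.10e-06, and p = 0.118 with an estimated correlation). Of 28 interferon response genes 22 were lower, 23 adjusted over the list alone (median −1.66; camera adjusted p = 6.29e-10, and p = 0.254 with an estimated correlation). Of 24 immediate early and heat shock genes 19 were higher, 21 adjusted over the list alone (median 1.97; camera adjusted p = 1.17e-12, and p = 0.118 with an estimated correlation). The cell cycle list, with a median of 1.02 for TSA against vehicle, had a median of 1.86 in MuSC against Sca1+ cells. Pax7, Myod1 and Myf5 were higher by 7.62 ± 0.36, by 6.25 ± 0.47 and at least 51.6-fold. Ly6a differed by −5.07 ± 0.20 and Cd34, which both gates select for, by −3.19 ± 0.19. The chosen Dmd probe was at least 10.8-fold higher, and its probes ranged in fitted log2 difference from 0.53 to 5.22. Itga7, also common to both gates, was higher in MuSC by 5.80 ± 0.21. Smarcd3 was higher by 3.14 ± 0.22, Smarcd2 and Fst differed by −1.45 ± 0.25 and −2.53 ± 0.42, and Smarcd1, at 0.25 ± 0.22, did not pass (limma adjusted p = 0.476).

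Last, the TSA difference was set against the difference between the populations. Among 6340 genes that differed by at least 1 log2 unit between the MuSC array and the vehicle Sca1+ array of slide 1, the TSA difference on slide 2, which shares no array with it, had the sign of the MuSC difference for 81.4% (r = 0.697 and Spearman's rho = 0.631 across genes, which are not independent replicates). On slide 1, where the vehicle array is shared, it was 88.8%. Simulated unchanged groups gave 84.4%, but there genes reach the cut through noise alone, part of it in the shared array. That value is no chance level for the real genes, many of which differ between the populations. The covariance on slide 1 was 0.566 across genes, beside 0.0810 in simulation. Of the 708 genes higher with TSA, 563 were also higher in MuSC, and of the 70 lower, 55 were also lower; independent lists would share 74.2 and 8.16, a value that leaves out the shared vehicle arrays, and simulated unchanged groups shared 0 calls, a value that leaves out the effects. These calls share both vehicle arrays, so part of the excess over independent lists may come from them, and the excess over neither value is called a shared effect. The fold changes correlated at 0.636 across genes, beside 0.412 in simulation, where no gene differed and the shared arrays alone correlate them. Their covariance was 0.582, beside 0.0409 in simulation and 0.553 with no shared array. TSA effects on the slides correlated at r = 0.729 across genes. Against MuSC itself, 2075 genes were higher and 1261 lower in TSA-treated Sca1+ cells (limma, adjusted p under 0.05); without replicate 2 of the TSA group 0 passed in limma, with 5287 at an unadjusted p under 0.05. Without replicate 1 of that group 381 were higher and 116 lower, and without either vehicle Sca1+ array 1532 and 798.

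**Figure D3:**
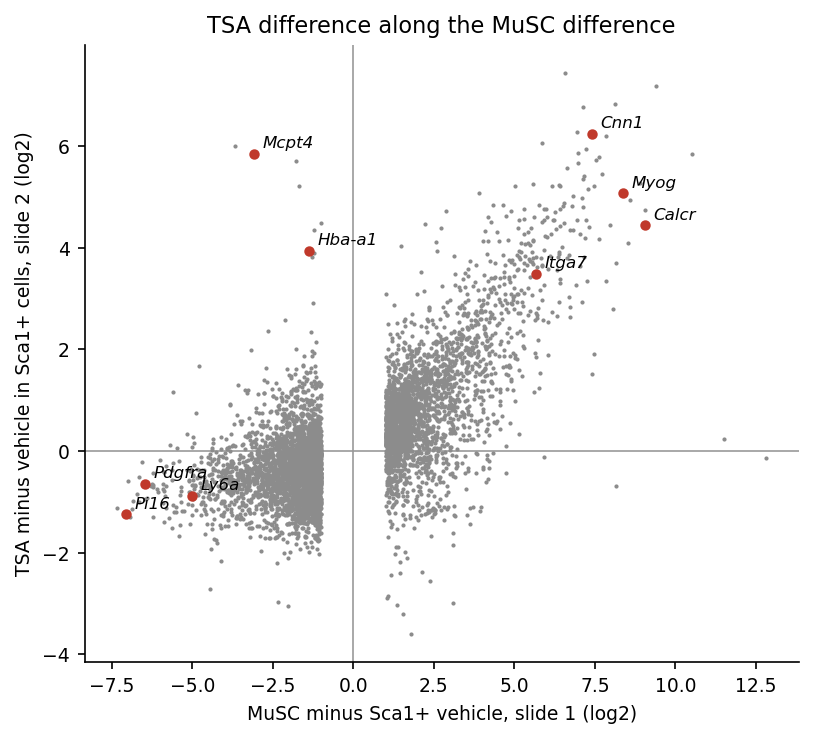
Each point is 1 of 6340 genes that differed by at least 1 log2 unit between the MuSC and vehicle Sca1+ arrays of slide 1 (horizontal axis, log2); the vertical axis is TSA minus vehicle in Sca1+ cells on slide 2 (log2), and larger points mark genes that are named. Of these genes 81.4% lie on the side of MuSC, with Mcpt4 and Hba-a1 above 0 on the vertical axis and below 0 on the horizontal.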

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

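Centring each array on the median of the kept genes, with the main values or with normexp, was chosen after seeing the data; the other alternatives were planned. The causes of the changes below were not tested, except where fewer arrays or genes enter. For TSA against vehicle (708 higher, 70 lower), normexp gave 1311 and 6526 (16.7% higher, against 91.0%), and with centring 1490 and 2131; no filter on dim probes gave 280 and 3, an intensity trend 1200 and 474, each probe alone 45 lower and the replicate block 165 lower. Samples share a number and a slide; deviations of the same number correlated at 0.347 across genes, and apart from this count the replicate block moved no count of calls by over 1.5 times. Leaving out 1 array, which leaves a lone sample assumed to vary like the other groups, gave 0 to 318 higher and 0 to 2 lower. For MuSC against Sca1+ cells, no filter gave 1571 higher and 1809 lower, and leaving out 1 array 1590 to 2003 and 1833 to 2276. For TSA-treated Sca1+ cells against MuSC, no filter gave 983 higher and 324 lower, normexp 1905 lower, the trend 2130 lower, and leaving out 1 array 0 to 1532 and 0 to 798. With an estimated correlation 0 of the 17 list calls for TSA and 0 of the 21 for MuSC held; with every other alternative, leaving out arrays included, 15 to 19 and 19 to 23 lists were called. The TSA effect along the MuSC minus Sca1+ difference (81.4% of genes on the side of MuSC) was 76.7% with normexp, 84.7% for genes well above background on all 5 arrays, 80.4% with the deposited values, 84.2% at a difference of at least 2 and 88.8% on slide 1. The slide agreement of the TSA effect (r = 0.729) was 0.702 with normexp, 0.490 with no filter, 0.735 for genes above background on all arrays and 0.719 with the mean of a gene's probes. With normexp Dmd turned to −0.19 and Il1b to −0.21, neither passing, and Dpf3 to −0.68, which passed (limma adjusted p = 0.0267). For the sorting gate list, with a median of −0.72 and a mean of 0.63, camera gave a downward direction without passing and fry called it higher (adjusted p = 0.00643). The list of granulocyte and mast cell markers turned lower, at −0.15, among genes above background on all arrays, without passing. Among the other values of named genes, 3514 kept their side of the threshold or moved by under 1 SD, 359 lost and 121 gained a call, and 120 moved further within a slide; for lists 839 kept it, 63 lost a call (38 of them with an estimated correlation) and 22 gained one. Signal over background limits the folds of dim probes to lower bounds.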

Other observations

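All tests of explanations here were chosen after the results were seen, except the normexp split of genes that differed at least 2-fold. Of the 708 genes higher with TSA, those with a symbol and not called higher in MuSC numbered 96 and were of several kinds, not tested for a theme; the ones below were chosen after their values were seen. Glycam1, a mucin of lymph node venules, was at least 41.7-fold higher, and Gp9, a platelet glycoprotein, at least 5.20-fold, while Slpi, a secreted inhibitor of leukocyte proteases, rose by 2.33 ± 0.15. The mesothelial genes Upk3b and Lrrn4 were at least 9.48-fold and 6.00-fold higher, and the B cell gene Ms4a1 at least 4.39-fold. Plin4, a lipid droplet protein, rose by 4.18 ± 0.16 and Egln3, an oxygen sensor, was at least 8.98-fold higher, and both were also higher in MuSC. The 2 probes of Egln3 gave fitted log2 differences of 1.77 and 3.17 with TSA, with 1 called higher. Spp1, which encodes osteopontin, rose by 1.79 ± 0.17 and was also higher in MuSC, and the chemokine Ccl11 fell by 1.17 ± 0.15. For the other lists, tested with limma camera, TSA gave medians of −0.48 for matrix proteases and their inhibitors (1 of 23 higher), −0.14 for TGF-beta signalling (2 of 29 higher; mean 0.05), 0.08 for adipogenesis (1 of 31 higher), −0.33 for paracrine regulators (1 higher and 1 lower of 33) and 0.04 for SWI/SNF (1 of 20 higher). The counts adjusted over the list alone were 5 higher and 11 lower, 5 and 5, 6 and 1, 2 and 4, and 1 and 0, in this order. Medians of the same test were −0.30 for interferon response (1 of 28 lower, also 1 adjusted over the list alone; adjusted p = 0.00949), 0.07 for chemokines (3 higher and 1 lower of 25, or 6 and 4 adjusted over the list alone) and −0.69 for complement (1 higher and 1 lower of 15, or 2 and 10 adjusted over the list alone; adjusted p = 0.015). Cholesterol synthesis and oxidative phosphorylation lay at 0.17 and 0.19 with 0 genes past limma's threshold by either adjustment (camera adjusted p = 0.015 and 0.0015). Glycolysis lay at 0.29 (2 of 24 higher, 6 adjusted over the list alone; limma camera adjusted p = 2.32e-05) and lymphocytes at 0.25 (2 of 11 higher, 3 adjusted over the list alone). Medians were −0.05 for tendon and 0.34 for 3 sex-linked genes, with 0 genes passing in limma by either adjustment, and −0.72 for the sorting gate (1 of 3 higher, or 1 higher and 2 lower adjusted over the list alone; mean 0.63). None of the 5 list calls named here held with an estimated correlation (the lowest adjusted p was 0.161), and the others did not pass.

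In TSA-treated Sca1+ cells 8 of 24 satellite cell, 22 of 35 sarcomere, 8 of 14 smooth muscle and 5 of 11 nerve genes were called higher. A lower share of the main Sca1+ type would raise the markers of every other type alike, unless the main type also expresses them. The sarcomere list rose by 1.76 log2 units more than the macrophage list. Their bootstrap 95% intervals, 1.85 to 3.34 and 0.55 to 0.69, also lay apart on each slide. This pair was chosen after its medians were seen. The satellite cell and nerve intervals, 0.06 to 2.05 and 0.32 to 3.11, overlapped that of the macrophage list. The smooth muscle interval, 0.81 to 4.57, did not, but on slide 2 it did (0.73 to 4.60 beside 0.43 to 0.78). The sarcomere values argue against a lower share of the main type as the only cause for that list, unless that type also expresses macrophage markers. For the satellite cell, nerve and smooth muscle lists a lower share of the main type stays open. The range over 10 marker lists, tried first, did not decide. On slide 1 the highest and lowest median lay 4.04 apart, beside 2.05 for the sum of their half-intervals. On slide 2 these values were 3.90 and 4.29. Cells of the kind sorted as MuSC among the TSA-treated Sca1+ cells stay open as a candidate explanation, although MuSC are Sca1-negative by the labels and the Sca1 gate would remove them: of 348 genes at least 4 log2 units higher on the MuSC array than on the vehicle array of slide 1, 96.3% were higher with TSA on slide 2, which shares no array with that choice, beside 50.6% in simulations without a TSA effect. Across the 312 of at least this difference from both vehicle arrays, TSA-treated Sca1+ cells differed from MuSC by a median of −2.03 with a robust SD of 0.843, beside 0.229 between the TSA arrays, a comparison that rests on 1 MuSC array from vehicle mice. The offset from MuSC was not the same for all genes. It was −1.32 for Cnn1 and −1.33 for Lmod1, but −3.47 for Myog, −4.43 for Calcr and −4.56 for Pax7. For Trim6, the largest increase in MuSC among the named genes, it was −10.25. Trim6 differed with TSA by 0.60 ± 0.50 (limma adjusted p = 0.487). A change of expression within Sca1+ cells under TSA also stays open and was not tested, since RNA from sorted cells in bulk does not tell them apart. Such a change could also raise 96.3% of the 348 genes, so that share does not favour cells of the MuSC kind over it.

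Several mast cell and haemoglobin genes and some plasma cell genes were higher with TSA on both slides, and the called ones were not called higher in MuSC. Of 15 mast cell markers listed after such genes had been seen among the largest increases, 13 were kept, of which 8 were called higher and 0 lower, while Mitf (−0.53 ± 0.17) and Mrgprb1 (−1.15 ± 0.85), neither past the threshold, were lower on both slides. Mitf already lay 2.52 log2 units above the 75th percentile in vehicle Sca1+ cells, where a small share of mast cells would be hidden. Mrgprb1 was well above background on only 1 array of each Sca1+ group. Of the 13, 8 were above background on both vehicle arrays, and 5 stood in a fixed list. Of the 7 in no fixed list and not named by the rule, 71.4% were higher with TSA on both slides, short of the 75% set as the mark of whole mast cells in the sort, which stay open; over all 13, the set tested first, the share was 84.6%. Of 13 plasma cell genes 11 were kept, 8 of them above background on both vehicle arrays and 1 in a fixed list. Of the 9 in no fixed list and not named by the rule, 33.3% were higher on both slides. Among them were both that were not above background on both vehicle arrays, Mzb1 and Pou2af1, neither past the threshold (limma adjusted p = 0.111 and 0.105). Plasma cells in the sort therefore stay open too (36.4% over all 11). Whether the gate on CD34 and α7-integrin removes such cells was not tested, and neither was an effect of TSA on these cells in the muscle.

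Far more genes were called higher than lower with TSA, and the TSA arrays were brighter. Among genes well above background on all 5 arrays 85.9% of the called genes were higher, which argues against dim probes as the whole cause. With normexp 81.8% of the called genes that differed at least 2-fold were higher, which argues against the background correction for such differences, although for smaller ones normexp called mostly lower genes. An effect of TSA stays open and was not tested apart from the makeup of the sort.

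By the α7-integrin gate in the labels both populations carry the protein, but Itga7 was 5.80 log2 units higher on the MuSC array than in vehicle Sca1+ cells.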
